A study of Homo sapiens with 8 samples.

How the data were processed

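Ribosome-bound messenger RNA from H2030-BrM cells was measured in 8 libraries, in 4 groups of 2 labelled biological replicates. The groups are control shRNA (against luciferase) in the dish, control shRNA on a brain slice, L1CAM shRNA in the dish and L1CAM shRNA on a brain slice. They are called shControl_dish, shControl_slice, shL1CAM_dish and shL1CAM_slice. Slice cells were collected after 48 h, and dish cells at 0 h, before seeding. Per the labels, a kit that selects poly-A RNA and does not mark the strand made the libraries, and each RNA sample had an integrity number above 9.5.

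The deposited table holds a normalized signal for 23368 gene symbols in 1 column per library, and 0 columns were left unused. The authors' processing notes name FastQC 0.11.3, HTSeq 0.5.4, DESeq2 without a version, and the builds hg19 and GRCh37. The aligner and the gene annotation are not given in the sources used here. Each column consisted of whole multiples of a single step, within a tolerance of 1e-06 and with a largest distance of 4.9e-10 from a whole number. The values are therefore read counts divided by 1 size factor per library, and the whole reads were recovered from them. The recovered reads came to between 13486212 and 16734651 per library. A count of 3 reads, which is the upper limit that a count of 0 allows, corresponded to a normalized count of 2.75 to 3.57. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The reference annotation at hand is of a later build, so no coordinates are given. It served only for gene names and transcript lengths, and 12386 of the 13010 tested genes (95.2%) had a length.

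Values were analysed as log2 of the normalized count plus a pseudocount of 1, and every log2 fold change is on that scale. Genes with a mean of at least 10 over the 8 libraries were tested, which left 13010. A single limma fit (limma 3.58.1 in R 4.3.3) estimated the 4 group means, with eBayes and an intensity trend, and 5 contrasts were drawn from it. These were slice against dish for each shRNA, L1CAM against control shRNA in each culture, and the interaction, which is the difference of the slice responses and equally of the knockdown effects. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. No replicate block was used, because nothing in the labels pairs the replicates across groups. With 2 libraries per group the groups share 1 estimate of the spread for each gene, which assumes that they vary alike. The replicates are labelled as biological replicates, but nothing states that they were separate cultures, so the p-values measure the spread between these samples.

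The samples' groups, the model, the filter, the thresholds, 38 gene lists and the rule for naming genes were all set before the data were examined. Lists with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 35 lists tested. Camera with an estimated correlation and fry were run beside it. Of the 3 lists not tested, the mitochondrially encoded transcripts had 0 members in the table. Markers of microglia and macrophages had 2 tested members, and markers of endothelial and mural cells had 1. Counts per list are given over all genes tested and adjusted over the list alone. Marker lists for cell types of the mouse brain were included because the slice is mouse tissue.

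Named genes follow this rule. L1CAM is named in every contrast. For the slice response with control shRNA and for both knockdown contrasts, the 8 largest rises and the 8 largest falls are named among genes past the threshold with a mean of at least 50 and with both libraries of one group above both of the other. For the other contrasts 5 and 5 are taken, and for a direction in which nothing passes, the 3 smallest p-values, as values. The slice contrasts add 5 rises among genes with a dish mean of at least 50. Each list described adds up to 4 members with the smallest p, or up to 6 for the YAP/TAZ and MRTF/SRF lists. Symbols that start with LOC, MIR or SNOR are skipped, and 2 genes that the rule covers are not reported.

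Alternatives planned in advance were pseudocounts of 10 and 0.25, no filter, a mean of at least 50, TMM and upper-quartile scaling, a replicate block, a fit of the 4 libraries compared, robust eBayes, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fit without brain markers and genes low in the dish, and each library left out in turn. Library weights, the removal of a transcript-length trend (a loess curve on log2 length in each library) and list counts without replicate 2 of shL1CAM_slice were added after the data were seen. For a pair of contrasts, the expected overlap is the product of the 2 counts over the genes tested, per direction. In addition, 50 simulated data sets with unchanged group means gave the overlap and correlation that shared libraries produce where no gene changes and all groups have the same spread.

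The steps were tested on simulated data in which 200 of 13010 genes were changed, 50 at each fold. Each gene had 1 dispersion, estimated from the real libraries and shared by all of them. The simulation therefore lacks the wider spread of shL1CAM_slice, and its shares do not cover that. In the slice contrast for control shRNA, 10% were recovered at a fold of 1.5, 56% at 2 and 100% at 4. For the knockdown on the slice the shares were 6%, 68% and 98%, in the dish 6%, 42% and 98%, and for the interaction 0%, 10% and 86%. Unchanged genes made up 2.26% to 10.3% of the calls. A list moved in the simulation was called, and 0 others were. Genes varied independently in it, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.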

Results

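Ribosome-bound messenger RNA was sequenced from H2030-BrM cells, a brain-metastatic derivative of the H2030 lung adenocarcinoma line. The cells expressed an EGFP-tagged ribosomal protein, so an antibody against EGFP could recover their ribosomes, and the RNA on them, from a lysate that also held mouse brain tissue. Control or L1CAM shRNA was combined with culture in the dish or 48 h on a mouse brain slice. L1CAM encodes a cell adhesion molecule of the nervous system. Each of the 4 groups had 2 libraries, 8 in all. Medium, serum, substrate and time differed together between dish (0 h) and slice (48 h).

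Recovered reads per library were 15838921 and 16253609 in shControl_dish, 15609989 and 13899903 in shControl_slice, 16734651 and 15076028 in shL1CAM_dish, and 15669035 and 13486212 in shL1CAM_slice. Between 6980 and 7585 of the 23368 genes were at 0 in a library. The SD across genes of the log2 difference between replicates was 0.288 in shControl_dish, 0.218 in shControl_slice, 0.303 in shL1CAM_dish and 0.637 in shL1CAM_slice. Replicate 2 of shL1CAM_slice stood apart. Relative to each gene's mean over 8 libraries, the 10% of genes with the shortest transcripts were higher in it by a median of 0.19 on the log2 scale, and the 10% with the longest were lower, at -0.58. Genes for cytosolic ribosomal proteins, whose transcripts are short, took 9.15% of its signal and 4.65% to 6.41% in the other 7 libraries. Counts that lead each comparison are therefore also given without this library, a choice made after the data were seen.

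**Figure D1:**
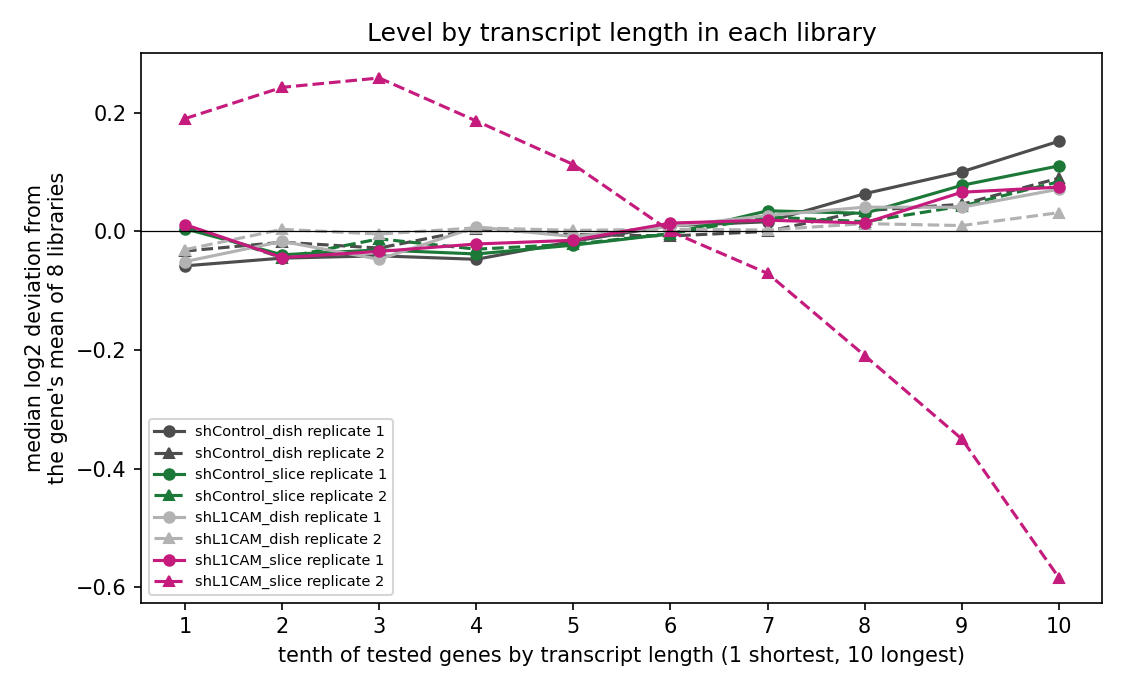
Median log2 deviation of genes from their mean over the 8 libraries (y axis), in 10 equal bins of the tested genes by transcript length (x axis), with 1 line per library. Replicate 2 of shL1CAM_slice runs from 0.19 in the shortest bin to -0.58 in the longest, with a peak of 0.26 between them, and the other 7 libraries stay between -0.06 and 0.15.

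L1CAM itself was lower in the cells with L1CAM shRNA in both cultures. Its normalized count was 461 ± 29.6 (SD, n = 2) in shControl_dish and 107 ± 26.9 (SD, n = 2) in shL1CAM_dish, a fold of 4.33 lower. On the slice it was 444 ± 9.30 (SD, n = 2) with control shRNA and 70.1 ± 6.56 (SD, n = 2) with L1CAM shRNA, a fold of 6.28 lower. The log2 fold change was -2.65 ± 0.21 (SE) on the slice (limma adjusted p = 0.00164) and -2.11 ± 0.21 in the dish (adjusted p = 0.00865). The call in the dish was lost when any of the 4 dish libraries was left out, with adjusted p = 0.167 and 0.163 without replicate 1 or 2 of shControl_dish and 0.104 and 0.191 without replicate 1 or 2 of shL1CAM_dish, while the log2 fold change stayed between -2.37 and -1.86. The slice did not move L1CAM past the threshold with control shRNA (-0.05, limma adjusted p = 0.888) or with L1CAM shRNA (-0.59, adjusted p = 0.0719).

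**Figure D2:**
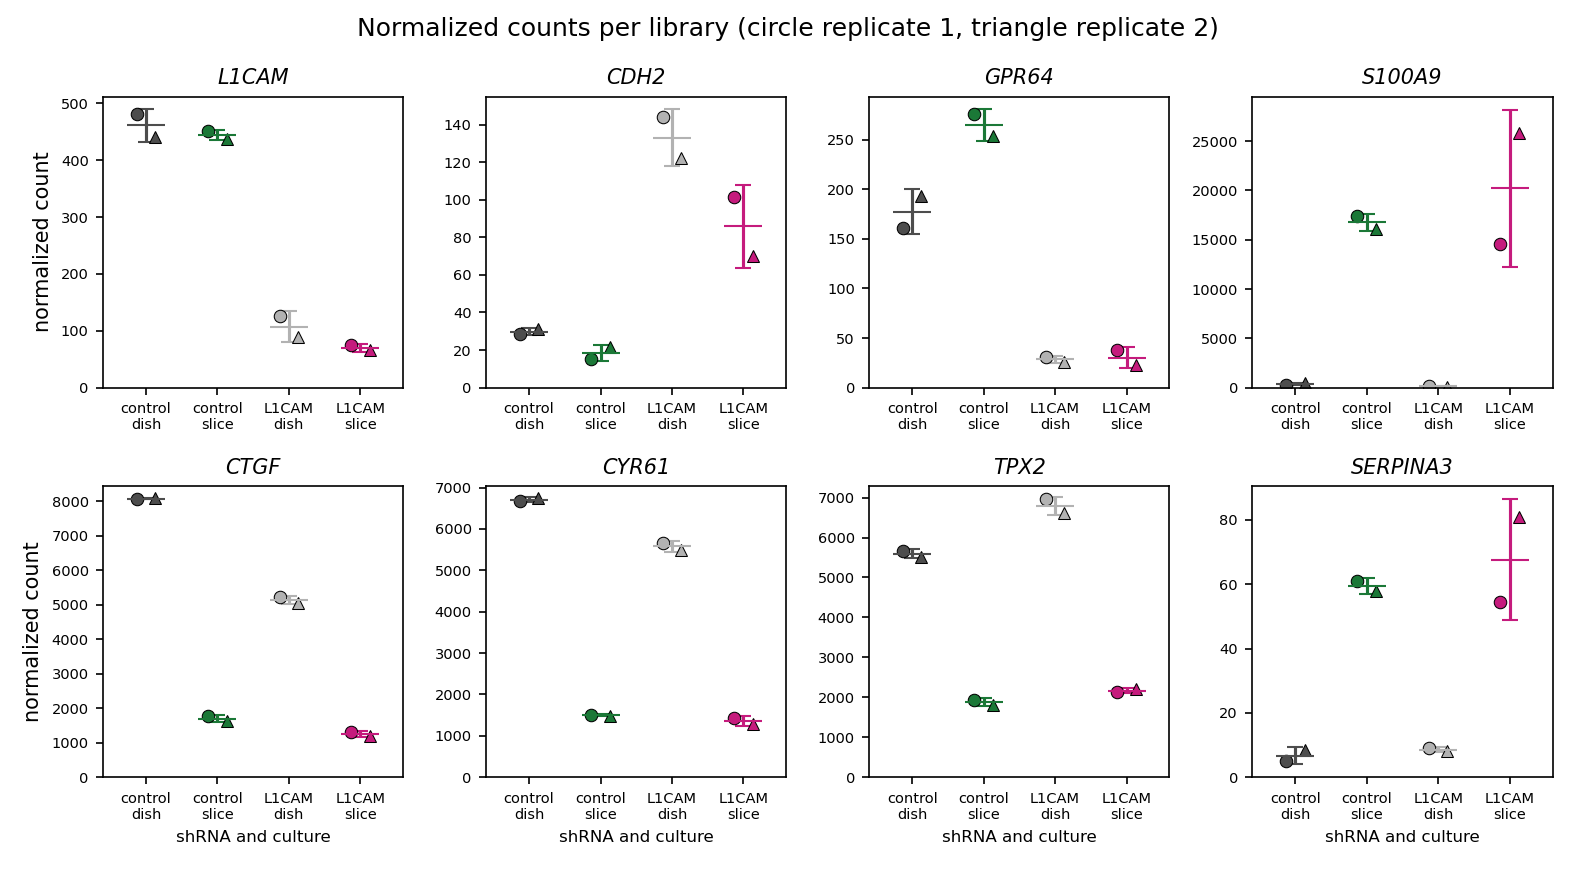
Normalized count (y axis, linear, from 0) of 8 named genes in the 4 groups (x axis). Points are libraries (circle for replicate 1, triangle for replicate 2), and bars give the mean and SD of 2 libraries. L1CAM lies at 65.4 to 126 in the cells with L1CAM shRNA and at 438 to 482 in those with control shRNA.

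The first comparison asks what 48 h on brain tissue changed in cells with control shRNA. Their libraries held far more of the inflammation-linked calcium-binding transcripts S100A9 and S100A8. They held less of G2/M genes such as TPX2 and of CTGF and CYR61, targets of the growth regulators YAP and TAZ. S100A9 rose from 351 ± 136 to 16753 ± 904 normalized counts (SD, n = 2 each), a log2 fold change of 5.63 ± 0.36 (SE; limma adjusted p = 0.000329). S100A8 rose from a count of 1.92, below the limit that 3 reads set, to 120 (limma adjusted p = 0.00026). The named builds are human, and mouse reads could make up most of a rise from so near 0. This was not tested gene by gene. CTGF, a secreted matrix protein and YAP/TAZ target, fell from 8078 ± 19.1 to 1702 ± 98.1 (SD, n = 2 each), a log2 fold change of -2.25 ± 0.13 (limma adjusted p = 0.00026). Of 13010 genes, 885 rose and 1045 fell. Of these, 307 rose and 362 fell by more than a factor of 2.

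Among the other large rises in control cells were FAM83A (3.09), S100A4 (2.96), the Notch ligand DLL4 (2.70), SUSD2 (2.67), the integrin subunit ITGA10 (2.65) and the interferon-inducible GTPase GBP2 (2.63). Among genes already at a count of 50 or more in the dish, ZNF467 (2.02), the receptor TNFRSF19 (1.97), the protease inhibitor SLPI (1.92), FAM107B (1.91) and the mucin MUC1 (1.87) were the named rises. The named falls were the collagen COL12A1 (-3.31), the matrix protein thrombospondin 1 (THBS1, -3.14), the spectrin SPTBN1 (-2.72), ANKRD2 (-2.69), MC5R (-2.63), the transporter SLC16A6 (-2.34), CTGF and GOLGA8A (-2.22).

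Genes of the cell cycle fell together in control cells. Of 46 G2/M genes 37 fell and 0 rose (42 and 0 adjusted over the list alone, 46 and 0 without replicate 2 of shL1CAM_slice), with a median log2 fold change of -1.05. The spindle protein TPX2 (-1.58 ± 0.13), the kinetochore protein NDC80 (-1.43) and HMMR (-1.89) were among them. Camera gave this list an adjusted p = 5.61e-27, and it was the list that kept its call with an estimated correlation (adjusted p = 0.0289). Of 39 G1/S genes 29 fell and 0 rose (35 and 0 adjusted over the list alone, 36 and 0 without that library), with a median of -0.82. The primase PRIM1 fell by 1.36, and the replication factor CDC6 by 1.18. Camera gave adjusted p = 3.67e-19 for the list, and adjusted p = 0.171 with an estimated correlation. Replication-dependent histone genes moved the other way, with 7 of 11 higher and 0 lower (9 and 1 adjusted over the list alone, 8 and 1 without that library). HIST2H2BE rose by 1.69 and HIST1H2AC by 1.61. Their median was 1.10 (camera adjusted p = 3.02e-05, and adjusted p = 0.442 with an estimated correlation). Because the kit selects poly-A RNA, histone transcripts without a poly-A tail were outside what these libraries measured. The values do not show how all histone transcripts changed.

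Targets of YAP and TAZ, the effectors of the Hippo pathway, lay lower on the slice in control cells. Of 24 targets 9 fell and 0 rose (10 and 0 adjusted over the list alone, 14 and 1 without replicate 2 of shL1CAM_slice), with a median of -0.55. CTGF, CYR61 (-2.16 ± 0.13), ANKRD1 (-3.06), the receptor AXL (-1.03), NUAK2 (-1.43) and AMOTL2 (-1.11) were among those that fell. Its camera adjusted p was 2.63e-06, with adjusted p = 0.442 with an estimated correlation. Of 38 cytoskeletal targets of MRTF and SRF, 7 fell and 1 rose (7 and 1 adjusted over the list alone, 15 and 4 without that library), with a median of -0.24. The actin crosslinker FLNA (-1.67), the myosin heavy chain MYH9 (-1.38), TLN1 (-0.84) and ACTN1 (-0.72) fell, and FHL1 rose (0.59). Camera gave adjusted p = 0.0285, and adjusted p = 0.661 with an estimated correlation. Without replicate 1 of shControl_dish the MRTF/SRF call was lost (adjusted p = 0.102, median -0.15).

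Immediate early genes went the other way in control cells, with 10 of 30 higher and 1 lower (12 and 3 adjusted over the list alone, 14 and 3 without replicate 2 of shL1CAM_slice). The members with the smallest p were feedback inhibitors of growth factor signalling, DUSP5 (1.29), SPRY4 (1.10) and DUSP6 (1.24), and the RNA-binding protein ZFP36 (0.93). The list's median was 0.26 (camera adjusted p = 0.0237, and adjusted p = 0.313 with an estimated correlation). In the STAT3 response list 4 of 13 rose and 1 fell (5 and 1 adjusted over the list alone, 8 and 1 without that library). BCL3 (1.40), CEBPD (1.09) and SOCS1 (1.65) rose. The list had a median of 0.38 (camera adjusted p = 0.0431, adjusted p = 0.442 with an estimated correlation, and 0.0548 without replicate 1 of shControl_dish). In the serpin and plasminogen list 2 of 9 rose and 0 fell (4 and 0 adjusted over the list alone, 4 and 1 without that library). SERPINA3, an acute-phase protease inhibitor, rose by 3.01 ± 0.34 to a count of 59.4, and S100A10 rose by 0.88. Mouse reads could also contribute to the rise of SERPINA3 at so low a count, which was not tested. The list's median was 0.29 (camera adjusted p = 0.0383, and adjusted p = 0.56 with an estimated correlation). Its adjusted p was 0.0557 without replicate 1 of shControl_dish, 0.0601 without replicate 1 of shControl_slice, and 0.0776 and 0.0783 without replicate 1 or 2 of shL1CAM_slice.

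Several groups of genes for energy supply and protein making were lower in control cells on the slice. Of 18 glycolysis genes 8 fell and 0 rose (8 and 0 adjusted over the list alone, 13 and 0 without replicate 2 of shL1CAM_slice), with a median of -0.38. The lactate transporter SLC16A1 (-0.93) and hexokinase HK1 (-1.04) were among them. Camera gave adjusted p = 0.000208, and adjusted p = 0.56 with an estimated correlation. Of 36 nuclear genes of oxidative phosphorylation 2 fell and 0 rose (2 and 0 adjusted over the list alone, 14 and 2 without that library), NDUFA9 (-0.71) and ATP5B (-0.56). Their list had a median of -0.17 (camera adjusted p = 0.0359, and adjusted p = 0.794 with an estimated correlation). Its adjusted p was 0.19 without replicate 2 of shControl_dish and 0.0628 without replicate 1 of shControl_slice. Of 24 ribosome biogenesis genes 12 fell and 0 rose (16 and 0 adjusted over the list alone, 22 and 0 without replicate 2 of shL1CAM_slice), with a median of -0.62. The nucleolar proteins NCL (-0.97), NOP58 (-0.93) and TCOF1 (-1.07) fell. Camera put this list at adjusted p = 3.15e-08, and adjusted p = 0.171 with an estimated correlation. Of 18 chaperones of the endoplasmic reticulum 3 fell and 0 rose (4 and 0 adjusted over the list alone, 11 and 1 without that library), among them HSPA5 (-0.86) and CANX (-0.73). Their list had a median of -0.45 (camera adjusted p = 0.0174, and adjusted p = 0.661 with an estimated correlation). Cytosolic ribosomal protein genes ran the other way, with 2 of 75 higher, RPL22 (0.54) and RPL12 (0.79), and 0 lower (0 and 0 adjusted over the list alone, 44 and 1 without that library). Their median was 0.29 (camera adjusted p = 0.000217, and adjusted p = 0.794 with an estimated correlation).

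The remaining 22 lists tested in control cells were not called, at camera adjusted p between 0.0544 and 0.986. They were the integrated stress and amino acid response, heat shock proteins, NF-kB and inflammatory cytokines, hypoxia response, p53 targets, fatty acid synthesis, antigen presentation, cholesterol and sterol synthesis, epithelial junctions and keratins, neurite-type cell adhesion molecules, Notch targets, type I interferon response, Wnt targets, metallothioneins and zinc transport, basement membrane and matrix, TGF-beta response, integrins and adhesion complex, mesenchymal markers and NRF2 targets, together with the markers of neurons, astrocytes and oligodendrocytes. The integrated stress and amino acid response was called lower without replicate 1 of shControl_dish (adjusted p = 0.016), replicate 2 of shControl_slice (0.0407), replicate 1 of shL1CAM_slice (0.038) or replicate 2 of shL1CAM_slice (0.0375), and the heat shock proteins without replicate 2 of shControl_dish (0.0275). Of the tested brain markers, 1 of 18 neuron markers rose and 1 fell, 1 of 8 astrocyte markers fell, and 1 of 6 oligodendrocyte markers rose and 1 fell (2 and 2, 0 and 1, and 3 and 1 adjusted over the list alone). Brain markers with a dish mean under 10 together had 107 and 93 reads in the shControl_dish libraries and 151 and 146 in the shControl_slice libraries, against 122 and 126 in shL1CAM_dish and 159 and 108 in shL1CAM_slice. The low neuron markers summed to a normalized count of 15.7 and 11.3 in shControl_dish and 41.1 and 38.5 in shControl_slice, the low astrocyte markers to 4.89 and 5.66, and 8.60 and 2.14, the low microglia and macrophage markers to 27.4 and 19.8, and 28.6 and 42.8, and the low endothelial and mural markers to 42.1 and 40.6, and 31.5 and 46.0. Sums are given for 4 of the 5 cell types. The cells themselves express some of these markers, with 11 of 32 neuron, 6 of 19 astrocyte and 3 of 18 oligodendrocyte markers at a dish mean of at least 50.

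The count of genes past the threshold in control cells depended on each library. Leaving out a library with L1CAM shRNA changes no fold change between the control groups, whose median stayed at 0.0129 on the log2 scale. It changes only the shared estimate of the spread. The count of 1930 genes became 7 and 128 without replicate 1 or 2 of shControl_dish, 65 and 58 without replicate 1 or 2 of shControl_slice, 1135 and 1127 without replicate 1 or 2 of shL1CAM_dish, and 6086 and 6109 without replicate 1 or 2 of shL1CAM_slice. Without replicate 2 of shL1CAM_slice, 3112 genes were higher and 2997 lower, and all 1930 genes were among them. COL12A1, CTGF, CYR61, HMMR, ITGA10, S100A8 and S100A9 stayed past the threshold whichever of the 8 libraries was left out, and they were the 7 genes left without replicate 1 of shControl_dish. Of the 125 genes past the threshold that the naming rule and the lists cover, 46 stayed past it without replicate 2 of shControl_dish, 33 and 32 without replicate 1 or 2 of shControl_slice, and 103 without replicate 1 or 2 of shL1CAM_dish.

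**Figure D3:**
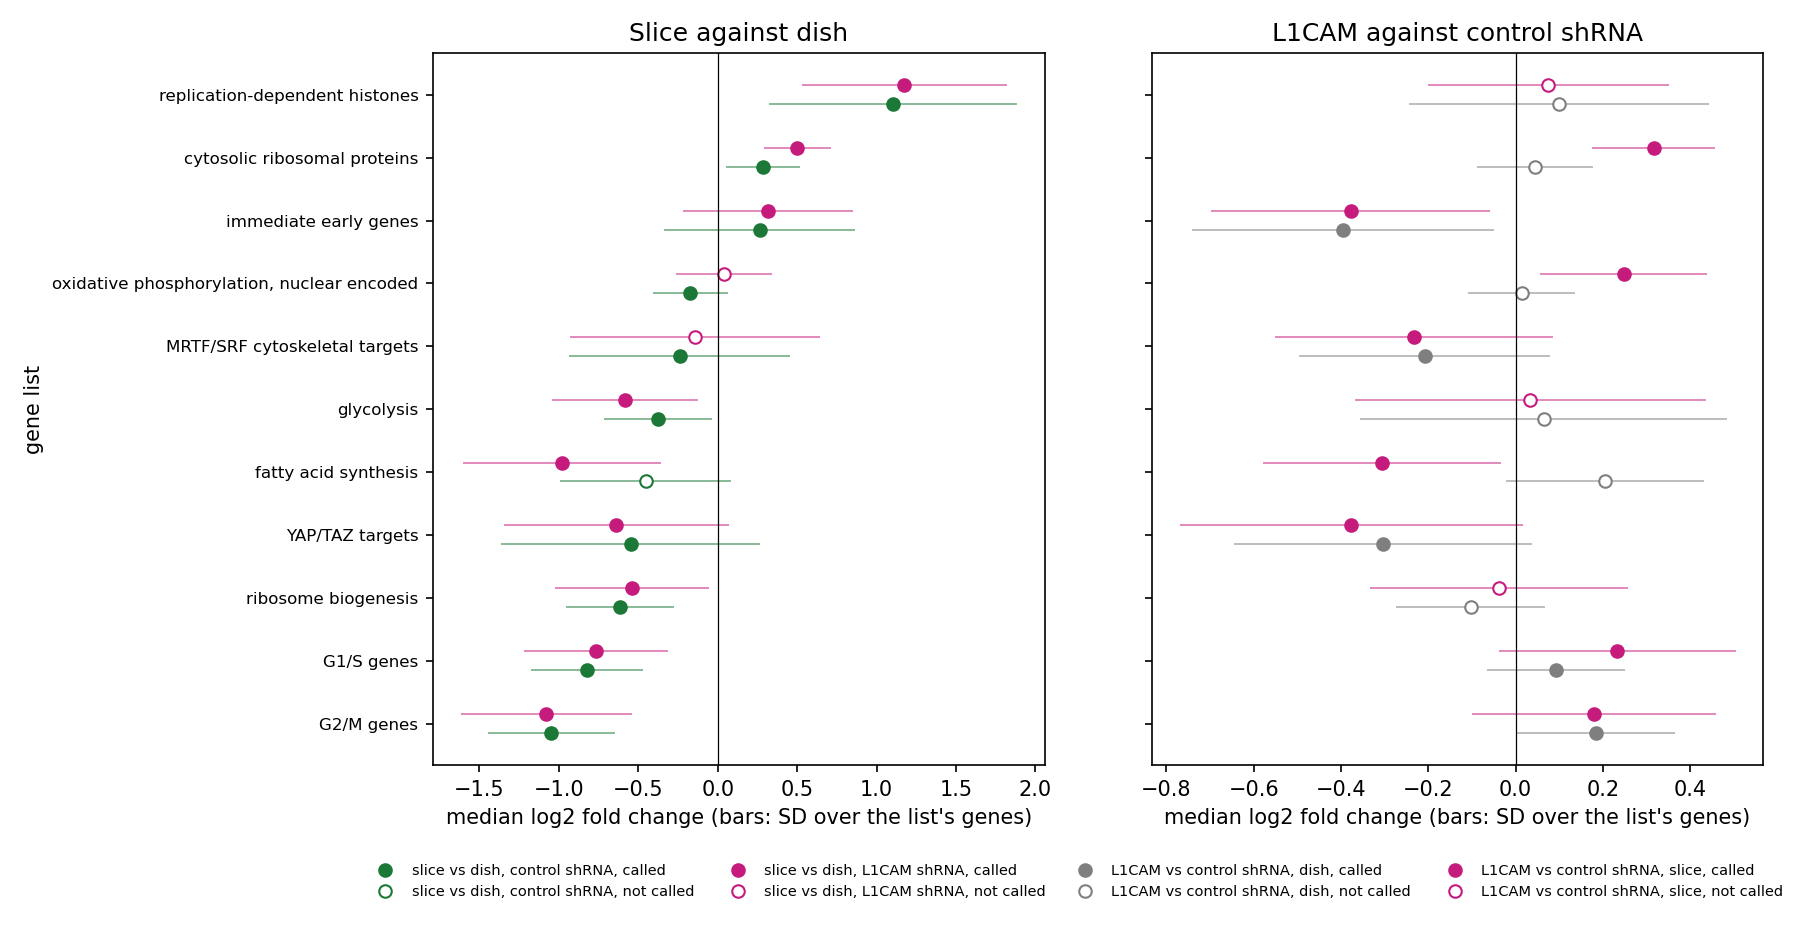
Median log2 fold change (x axis) of the gene lists called in at least 2 of the 4 contrasts (y axis), for slice against dish (left) and for L1CAM against control shRNA (right). Filled points passed camera's threshold with the preset correlation, open points did not, and lines give the SD over the list's genes. The G2/M list lies at -1.05 and -1.08 in the left panel, and the YAP/TAZ list lies below 0 in all 4 contrasts.

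The second comparison asks what the slice changed in cells with L1CAM shRNA. S100A9 (7.12 ± 0.36), S100A8 (from a count of 2.88 to 351) and FAM83A (5.13 ± 0.31) were the largest named rises, and COL12A1 (-3.80 ± 0.25) and THBS1 (-3.27 ± 0.36) the largest named falls. Of 13010 genes, 1312 rose and 1463 fell (limma), 429 and 620 of them by more than a factor of 2. The fit assumes equal spread in the 4 groups. With the 4 libraries compared alone limma called 510 genes, and with library weights 975. SUSD2 (3.49) and DLL4 (3.31) were the next named rises, and MC5R (-3.00), the lipoprotein receptor VLDLR (-2.95) and SPTBN1 (-2.89) the next named falls. Of these, SUSD2 was 4.45 and 2.53 without replicate 1 or 2 of shL1CAM_dish, and without replicate 1 or 2 of shL1CAM_slice THBS1 was -3.85 and -2.68 and VLDLR -3.87 and -2.03. Among genes at a count of 50 or more in the dish, S100A4 (2.68), SLPI (2.67), RGS6 (2.65), TNFRSF19 (2.51) and ZNF467 (2.41) were the named rises.

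Of 46 G2/M genes 38 fell in these cells and 0 rose (40 and 0 adjusted over the list alone, 44 and 0 without replicate 2 of shL1CAM_slice). TPX2 fell by 1.65, HMMR by 2.34 and the proliferation marker MKI67 by 2.27. The list's median was -1.08 (camera adjusted p = 2.56e-22, and adjusted p = 0.0417 with an estimated correlation). Of 39 G1/S genes 27 fell and 0 rose (31 and 0 adjusted over the list alone, 34 and 0 without that library), RRM1 by 1.53 (median -0.77, camera adjusted p = 1.34e-12, and adjusted p = 0.265 with an estimated correlation). Of 24 YAP/TAZ targets 10 fell and 0 rose (14 and 0 adjusted over the list alone, 13 and 2 without that library), CYR61 by 2.04, CTGF by 2.05 and AXL by 1.29 (median -0.64, camera adjusted p = 3.03e-07, and adjusted p = 0.488 with an estimated correlation). Of 24 ribosome biogenesis genes 14 fell and 0 rose (17 and 0 adjusted over the list alone, 20 and 0 without that library), among them NCL (-1.02) and NAT10 (-1.16), with a median of -0.54 (camera adjusted p = 6.24e-06, and adjusted p = 0.265 with an estimated correlation). Of 18 glycolysis genes 9 fell and 0 rose (9 and 0 adjusted over the list alone, 14 and 0 without that library), among them SLC16A1 (-1.27) and HK1 (-1.44). Their median was -0.58, and -0.38 without replicate 1 of shL1CAM_dish (camera adjusted p = 0.000585, adjusted p = 0.559 with an estimated correlation, and 0.154 without replicate 1 of shL1CAM_slice).

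Of 11 genes of fatty acid synthesis 7 fell in these cells and 1 rose (8 and 1 adjusted over the list alone, 9 and 1 without replicate 2 of shL1CAM_slice). The regulator SREBF1 fell by 1.03, the elongase ELOVL5 by 1.00, ACLY by 1.18 and the fatty acid synthase FASN by 0.98. The list's median was -0.98, and -0.56 without that library (camera adjusted p = 0.000594, and adjusted p = 0.488 with an estimated correlation). Immediate early genes were higher, with 9 of 30 up and 0 down (10 and 1 adjusted over the list alone, 10 and 2 without that library), among them DUSP5 (1.39) and IER3 (1.03), with a median of 0.32 (camera adjusted p = 0.0148, and adjusted p = 0.265 with an estimated correlation). Histone genes rose in 8 of 11 cases and fell in 0 (8 and 0 adjusted over the list alone, 8 and 1 without that library), HIST2H2BE by 1.67 (median 1.17, camera adjusted p = 3.2e-05, and adjusted p = 0.488 with an estimated correlation). Of 75 ribosomal protein genes 14 rose and 0 fell (20 and 0 adjusted over the list alone, 20 and 1 without that library), among them RPL22 (0.68) and RPL10 (0.86). Their median of 0.50 was 0.17 without that library, in which these genes took 9.15% of the signal, and 0.87 without replicate 1 of the same group (camera adjusted p = 2.15e-10, and adjusted p = 0.707 with an estimated correlation). The MRTF/SRF list, with 12 of 38 lower and 2 higher (13 and 3 adjusted over the list alone), was not called (adjusted p = 0.0603), but was called without replicate 1 of shL1CAM_dish (adjusted p = 0.00744) and without replicate 2 of shL1CAM_slice (adjusted p = 0.00713, median -0.28 against -0.14), and with the length trend removed (adjusted p = 0.0285). The serpin (adjusted p = 0.1), STAT3 (0.198), oxidative phosphorylation (0.966) and endoplasmic reticulum chaperone (0.222) lists, called in control cells, were not called here, and neither were the other 21 lists. Without replicate 2 of shL1CAM_dish 6 lists came to be called lower, the chaperones (0.0108), basement membrane (0.00732), neurite-type adhesion (0.00732), hypoxia (0.00796), integrated stress (0.00864) and TGF-beta (0.0171) lists. Without replicate 1 of shL1CAM_slice neurite-type adhesion was called lower (0.0296) and oxidative phosphorylation higher (0.00685). Without replicate 2 of shL1CAM_slice oxidative phosphorylation (0.00158), antigen presentation (0.00713) and integrated stress (0.00753) were called lower, and STAT3 (0.0354) and p53 targets (0.0494) higher.

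The count of 2775 genes in cells with L1CAM shRNA became 341 and 595 without replicate 1 or 2 of shL1CAM_dish, 7503 without replicate 1 of shL1CAM_slice, and 5039 without replicate 2 of shL1CAM_slice (2541 higher and 2498 lower). It became 1691 and 1685 without replicate 1 or 2 of shControl_dish, and 1465 and 1464 without replicate 1 or 2 of shControl_slice. Of the 140 genes past the threshold that the naming rule and the lists cover, 67 and 84 stayed past it without replicate 1 or 2 of shL1CAM_dish, 122 without replicate 1 or 2 of shControl_dish, and 116 without replicate 1 or 2 of shControl_slice. The slice response was shared between the shRNAs. Of the genes past the threshold in both contrasts, 700 rose in both and 809 fell in both, where independent lists would share 89.2 and 118, and 0 went opposite ways (335 without replicate 1 of shL1CAM_slice and 1 without replicate 2). Of the 1930 genes called in control cells, 1927 (99.8%) had the same sign with L1CAM shRNA, and 83.6% of those called without replicate 1 of shL1CAM_slice did. Across the 13010 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.829. The shared count of 1509 became 7 and 125 without replicate 1 or 2 of shControl_dish, 64 and 57 without replicate 1 or 2 of shControl_slice, 315 and 469 without replicate 1 or 2 of shL1CAM_dish, and 3870 and 4323 without replicate 1 or 2 of shL1CAM_slice.

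The third comparison asks which transcripts differed with L1CAM shRNA on the slice. Dependence on L1CAM there is the stated subject of the series. The labels give nothing to separate an effect of losing L1CAM from an effect of the hairpin on other genes. With L1CAM shRNA the cells on the slice carried more ribosome-bound transcript of the adhesion molecule N-cadherin. They carried less of the transcripts of the adhesion receptor GPR64 and of the cytokine IL18. N-cadherin (CDH2) rose from 18.3 ± 4.33 to 85.8 ± 22.1 normalized counts (SD, n = 2 each), a log2 fold change of 2.16 ± 0.28 (SE; limma adjusted p = 0.0218). GPR64 fell from 265 ± 15.9 to 30.2 ± 10.8, a log2 fold change of -3.13 ± 0.27 (limma adjusted p = 0.00262), and IL18 from 1468 ± 55.8 to 282 ± 51.1 (-2.39 ± 0.16, adjusted p = 0.00164). Of 13010 genes, 20 rose and 64 fell. The fit assumes equal spread in the 4 groups, but the replicate SD was 0.637 in shL1CAM_slice and 0.218 in shControl_slice. With the 4 slice libraries alone, and so fewer to estimate the spread, limma called 0 genes. With library weights it called 48.

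The other named rises on the slice were the retinol transporter STRA6 (1.75), the peroxidase GPX3 (1.68), S100A16 (1.54), the heparan sulfatase SULF2 (1.45), the transcription factor MNX1 (1.39), the cytokine IL15 (1.30) and LINC00473 (1.22). After GPR64 and L1CAM, the other named falls were PLLP (-2.65), UNC13A, which primes synaptic vesicles (-2.57), IL18, the netrin NTN4 (-2.29) and the sorting receptor SORL1 (-2.07). UNC13A stood at 3753 ± 3.71 with control shRNA and 643 ± 180 with L1CAM shRNA (SD, n = 2 each).

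No called list had more than 1 member past the threshold here, and the calls rest on members that lean the same way. YAP/TAZ targets lay lower, with 20 of 24 below 0 and 0 of 24 past the threshold (0 higher and 7 lower adjusted over the list alone, and 2 lower over all genes without replicate 2 of shL1CAM_slice). Their median was -0.38, and -0.16 without that library (camera adjusted p = 0.00041, and adjusted p = 0.654 with an estimated correlation). NT5E had the smallest p among them (-0.79, adjusted p = 0.062). Immediate early genes lay lower, with 27 of 30 below 0 and 0 past the threshold (0 and 5 adjusted over the list alone, and 8 lower without that library), TRIB1 at -0.84 and FOS at -0.86. Their median was -0.38 (camera adjusted p = 1.67e-05, and adjusted p = 0.178 with an estimated correlation). Of 38 MRTF/SRF targets 1 fell, FHL1 (-1.09), and 0 rose (1 and 0 adjusted over the list alone, 5 and 0 without that library), with a median of -0.23 (camera adjusted p = 0.00071, and adjusted p = 0.654 with an estimated correlation). Integrins and their adhesion complex lay lower (median -0.28, 0 of 22 past the threshold, 5 lower adjusted over the list alone, 3 lower and 1 higher without that library), with ITGA2 at -1.59 (limma adjusted p = 0.103). Without replicate 1 or 2 of shL1CAM_slice ITGA2 passed, at -2.23 and -0.96. For this list camera gave adjusted p = 0.0163, and adjusted p = 0.604 with an estimated correlation. Genes of fatty acid synthesis lay lower in 11 of 11 cases (median -0.31, 0 past the threshold, 2 lower adjusted over the list alone, 1 lower without that library), with FADS1 at -0.73. Camera gave adjusted p = 0.00688, and adjusted p = 0.654 with an estimated correlation.

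Genes of G1/S (median 0.23, camera adjusted p = 0.000519) and G2/M (median 0.18, adjusted p = 0.00773) lay higher on the slice with L1CAM shRNA, with 0 of 39 and 0 of 46 past the threshold (0 and 0 adjusted over the list alone, 2 and 2 higher without replicate 2 of shL1CAM_slice). Both had adjusted p = 0.654 with an estimated correlation. Ribosomal proteins (median 0.32, camera adjusted p = 1.44e-06) and oxidative phosphorylation (median 0.25, adjusted p = 0.00161) also lay higher, with 0 of 75 and 0 of 36 past the threshold (0 and 0 adjusted over the list alone). With an estimated correlation both had adjusted p = 0.737. Without replicate 2 of shL1CAM_slice both calls were lost and the medians turned to -0.05 (adjusted p = 0.178) and -0.02 (adjusted p = 0.65). Without replicate 1 of shL1CAM_slice these medians were 0.65 and 0.57, and the calls of 6 lists were lost, with adjusted p = 0.0754 for the immediate early genes, 0.166 for MRTF/SRF targets, 0.097 for integrins, 0.0791 for fatty acid synthesis and for G1/S, and 0.489 for G2/M. The G2/M call was also lost without replicate 2 of shControl_slice (adjusted p = 0.0512). The other 26 lists were not called (camera adjusted p between 0.0773 and 0.914), brain cell markers among them at 0.237 to 0.412. Chaperones of the endoplasmic reticulum were called higher without replicate 1 of shL1CAM_dish (adjusted p = 0.04996) or replicate 2 of shL1CAM_slice (0.0223), and epithelial genes lower without the latter (0.00391).

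The count of 84 genes became 11 without replicate 1 or replicate 2 of shControl_dish, 4 and 6 without replicate 1 or 2 of shControl_slice, 7 without replicate 1 or replicate 2 of shL1CAM_dish, 6896 without replicate 1 of shL1CAM_slice, and 607 without replicate 2 of shL1CAM_slice (196 higher and 411 lower, all 84 among them). L1CAM, IL18, NTN4 and UNC13A stayed past the threshold whichever of the 8 libraries was left out. Of the 23 covered genes that passed, 6 stayed past it without any 1 dish library or without replicate 2 of shControl_slice.

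The fourth comparison gives the effect of L1CAM shRNA in the dish, before seeding. The transcript of N-cadherin rose, and those of PLLP and GPR64 led the named falls. CDH2 rose from 29.7 ± 1.95 to 133 ± 15.1 normalized counts (SD, n = 2 each), a log2 fold change of 2.12 ± 0.28 (SE; limma adjusted p = 0.0283). PLLP fell from 1004 ± 14.4 to 151 ± 22.8 (-2.74 ± 0.23, limma adjusted p = 0.00594) and GPR64 from 177 ± 22.6 to 28.6 ± 3.57 (-2.59 ± 0.27, adjusted p = 0.011). Of 13010 genes, 12 rose and 28 fell. The other named rises were NWD1 (2.36), STRA6 (1.95), the extracellular protein cochlin (COCH, 1.84), S100A16 (1.65), GPX3 (1.53), C15orf52 (1.41) and the splicing factor NOVA1 (1.35). The other named falls were L1CAM, UNC13A (-2.05), NTN4 (-1.97), IL18 (-1.96) and SIRPB1 (-1.88).

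Immediate early genes lay lower in the dish with L1CAM shRNA, with 28 of 30 below 0. EGR1 fell (-0.97 ± 0.15, limma adjusted p = 0.0444) and 0 rose (7 lower and 0 higher adjusted over the list alone, 13 and 0 without replicate 2 of shL1CAM_slice). The median was -0.39 (camera adjusted p = 3.68e-10, and adjusted p = 0.0529 with an estimated correlation). NF-kB targets and inflammatory cytokines lay lower, with IL8 fallen (-1.11) and 0 risen (7 lower and 2 higher adjusted over the list alone, 10 and 2 without that library). Their median was -0.45 (camera adjusted p = 8.39e-05, and adjusted p = 0.152 with an estimated correlation). YAP/TAZ targets lay lower, with 0 of 24 past the threshold (3 lower adjusted over the list alone, 8 without that library) and CTGF at -0.65 (median -0.30, camera adjusted p = 0.000449, and adjusted p = 0.457 with an estimated correlation). MRTF/SRF targets lay lower, with 0 of 38 past the threshold (2 lower adjusted over the list alone, 9 without that library) and FHL2 at -0.95 (median -0.21, and -0.13 without replicate 1 of shControl_dish, camera adjusted p = 2.09e-05, and adjusted p = 0.355 with an estimated correlation). Genes of sterol synthesis lay higher in 22 of 24 cases, with 0 past the threshold (0 adjusted over the list alone, 7 higher without that library) and DHCR7 at 0.58 (median 0.29, and 0.19 without replicate 1 of shL1CAM_dish, camera adjusted p = 3.04e-06, and adjusted p = 0.268 with an estimated correlation). G2/M genes lay higher in 41 of 46 cases, with 0 past the threshold (0 adjusted over the list alone, 9 higher and 1 lower without that library; median 0.18, camera adjusted p = 6.73e-05, and adjusted p = 0.255 with an estimated correlation). These 6 lists stayed called whichever of the 8 libraries was left out.

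A further 6 lists were called in the dish with 0 members past the threshold, and each was lost without some library. The TGF-beta response (median 0.14, camera adjusted p = 0.0452) came to adjusted p = 0.0655 without replicate 1 of shControl_dish, 0.156 without replicate 1 of shL1CAM_dish, and 0.0881 and 0.0898 without replicate 1 or 2 of shL1CAM_slice. G1/S genes (median 0.09, adjusted p = 0.0323) came to 0.414 without replicate 2 of shControl_dish and 0.255 without replicate 2 of shL1CAM_dish. The type I interferon response (median 0.18, adjusted p = 0.031) came to 0.453 without replicate 1 of shControl_dish, 0.329 without replicate 1 of shL1CAM_dish, and 0.0568 and 0.0563 without replicate 1 or 2 of shL1CAM_slice. Antigen presentation (median 0.22, adjusted p = 0.0231) came to 0.13 without replicate 1 of shControl_dish and 0.19 without replicate 1 of shL1CAM_dish. Notch targets (median -0.30, adjusted p = 0.0189) came to 0.0598 without replicate 2 of shControl_dish, 0.0952 without replicate 2 of shL1CAM_dish, and 0.0695 and 0.0712 without replicate 1 or 2 of shL1CAM_slice. Wnt targets (median -0.36, adjusted p = 0.0452) came to 0.0732 and 0.0933 without replicate 1 or 2 of shControl_dish, 0.0532 without replicate 1 or 2 of shControl_slice, 0.139 without replicate 2 of shL1CAM_dish, and 0.0568 and 0.0563 without replicate 1 or 2 of shL1CAM_slice. Medians that moved by over 1.5 times were those of TGF-beta (0.06 and 0.27 without replicate 1 or 2 of shL1CAM_dish), G1/S (0.19 and 0.15 without replicate 1 of shControl_dish or of shL1CAM_dish), interferon (0.05 and 0.30 without replicate 1 or 2 of shControl_dish, 0.07 without replicate 1 of shL1CAM_dish), antigen presentation (0.13 and 0.12 without replicate 1 of shControl_dish or of shL1CAM_dish) and Notch (-0.13 without replicate 2 of shL1CAM_dish). With an estimated correlation the 6 had adjusted p between 0.355 and 0.527. Members past the threshold adjusted over the list alone were 7 higher and 1 lower for TGF-beta, 1 higher for interferon, 1 lower for Notch and 1 of each for Wnt targets, and 0 for the rest. Over all genes and without replicate 2 of shL1CAM_slice they were 7 higher and 2 lower for TGF-beta, 2 higher for G1/S, 3 higher and 1 lower for interferon, 2 higher for antigen presentation, 1 lower for Notch, and 1 higher and 3 lower for Wnt targets. The other 23 lists were not called (camera adjusted p between 0.0578 and 0.99), brain cell markers among them at 0.0689 to 0.218. Leaving out 1 library brought in up to 7 of them, without replicate 2 of shL1CAM_dish, among these the markers of astrocytes (adjusted p = 0.00651) and oligodendrocytes (0.0306). It brought in 3 without replicate 1 of shL1CAM_dish, and 1 each without replicate 2 of shControl_dish or either library of shL1CAM_slice.

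The count of 40 genes in the dish became 0 without replicate 1 or replicate 2 of shControl_dish, 0 without replicate 1 or replicate 2 of shL1CAM_dish, 8 without replicate 1 or replicate 2 of shControl_slice, 1436 without replicate 1 of shL1CAM_slice, and 1437 without replicate 2 of shL1CAM_slice (584 higher and 853 lower, all 40 among them). Of the 21 covered genes that passed, 0 stayed past the threshold without any 1 dish library and 6 without replicate 1 or 2 of shControl_slice. In limma 1217 genes had an unadjusted p under 0.05, edgeR called 77 genes and DESeq2 184. The knockdown effect overlapped between the cultures. Of the genes past the threshold in both, 7 rose in both and 21 fell in both, where independent lists would share 0.0184 and 0.138, and 0 went opposite ways (50 without replicate 1 of shL1CAM_slice and 1 without replicate 2). All 40 genes called in the dish had the same sign on the slice. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.649. The shared count of 28 became 0 without any 1 of the 4 dish libraries, 4 and 6 without replicate 1 or 2 of shControl_slice, and 998 and 441 without replicate 1 or 2 of shL1CAM_slice.

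The interaction asks whether the knockdown effect differed between slice and dish. No gene passed in limma (0 of 13010, smallest adjusted p = 0.97), where 162 genes had an unadjusted p under 0.05, and edgeR and DESeq2 each called 0. The smallest p-values belonged to FAM83A (2.04 ± 0.44), the protease inhibitor SERPINE2 (0.79 ± 0.20) and RASD1 (1.25 ± 0.31) on the positive side, and to CORO2A (-1.25 ± 0.31), the interferon-induced IFIT1 (-1.22 ± 0.32) and the desaturase FADS1 (-0.81 ± 0.21) on the negative side. The count was 4136 without replicate 1 of shL1CAM_slice, which leaves its arm with the library that stood apart, and 0 without any other library. For L1CAM the interaction was -0.54 ± 0.29 (limma adjusted p = 0.97). Camera called 10 lists, 4 higher and 6 lower, and 0 with an estimated correlation. They include fatty acid synthesis (median -0.42, camera adjusted p = 6.66e-07, adjusted p = 0.373 with an estimated correlation) and cholesterol and sterol synthesis (median -0.30, camera adjusted p = 4.76e-06, adjusted p = 0.373 with an estimated correlation, and 0.235 without replicate 1 of shL1CAM_slice). In these lists 0 of 11 and 0 of 24 members passed (2 lower and 0 adjusted over the list alone, 0 and 0 without replicate 2 of shL1CAM_slice). YAP/TAZ targets (median -0.07, adjusted p = 0.346) and MRTF/SRF targets (median 0.01, adjusted p = 0.924) were not called, but the YAP/TAZ list was called lower without replicate 1 of shL1CAM_slice (adjusted p = 0.049). Of the 25 uncalled lists, 6 came to be called without replicate 2 of shL1CAM_slice, 3 without replicate 2 of shL1CAM_dish, and 1 each without replicate 1 of shL1CAM_dish or either library of shControl_dish.

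Genes that the slice moved in control cells were also compared with the knockdown on the slice. Of them, 13 that rose on the slice fell with L1CAM shRNA and 3 that fell on the slice rose, where independent lists would share 4.35 and 1.61, and 7 moved the same way. Both contrasts use the shControl_slice libraries, which alone makes opposite signs more frequent. In 50 simulated data sets with unchanged groups the mean r was -0.501, against an observed r of -0.077. Their mean count of 0 follows from leaving every group unchanged, so it is no reference for the observed count. The simulations hold no slice response, so they do not show what shared libraries give where one is present. The covariance was -0.0198, and -0.0321 in the simulations. The simulations gave each gene 1 spread for all groups, while the replicate SD was 0.218 in shControl_slice and 0.637 in shL1CAM_slice. Their r and covariance therefore do not show what sharing the shControl_slice libraries, which varied least, gives in these data. The count of 16 became 0 without any 1 of the 4 libraries with control shRNA, 1 without replicate 1 or replicate 2 of shL1CAM_dish, and 1816 and 258 without replicate 1 or 2 of shL1CAM_slice, where 1657 and 115 moved the same way.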

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

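The length-removal tests were chosen only after the result was seen, as was the use of the estimated correlation, run as planned for every list, among the tests that weigh the sterol genes. The results here are differences between the knockdown effect on the slice and in the dish, each tested as the interaction on a list of genes. In each of these 10 lists 0 members passed by themselves in limma, and camera called 0 of the lists with an estimated correlation.

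Genes of cholesterol and sterol synthesis lay above 0 with L1CAM shRNA in 22 of 24 cases in the dish and in 12 of 24 on the slice, with a median interaction of -0.30 (camera adjusted p = 4.76e-06). The transcript-length trend of replicate 2 of shL1CAM_slice as the whole cause is argued against by adjusted p = 1.77e-07 with the trend removed, and by 2.92e-13 without that library. A single dish library as the cause of the higher level in the dish is argued against by the 4 pairs of an shL1CAM_dish and an shControl_dish library. Their medians were all above 0, at 0.403 and 0.312 with replicate 1 of shL1CAM_dish and 0.238 and 0.159 with replicate 2. The pairs reuse the same 4 libraries and hold no slice library, so they do not test the interaction itself. What stays open is that the genes vary together between replicates, since the estimated correlation of 0.0929 gave adjusted p = 0.373, and the call was also lost without replicate 1 of shL1CAM_slice (adjusted p = 0.235). An effect of losing L1CAM also stays open and untested, and the labels give nothing to separate it from an effect of the hairpin on other genes.

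Genes of fatty acid synthesis differed by a median of -0.42 (camera adjusted p = 6.66e-07, and adjusted p = 0.373 with an estimated correlation), and stayed called without each of the 8 libraries. Cytosolic ribosomal proteins differed by 0.23 (camera adjusted p = 3.35e-07, and adjusted p = 0.851 with an estimated correlation), which turned to -0.13 without replicate 2 of shL1CAM_slice (adjusted p = 1.25e-05) and was 0.62 without replicate 1. Oxidative phosphorylation differed by 0.21 (camera adjusted p = 0.000343, and adjusted p = 0.851 with an estimated correlation), which turned to -0.06 without replicate 2 of shL1CAM_slice (adjusted p = 0.0961) and was 0.48 without replicate 1 and 0.14 without replicate 2 of shControl_dish. The TGF-beta response differed by -0.24 (camera adjusted p = 0.00133, adjusted p = 0.373 with an estimated correlation, and 0.128 without replicate 1 of shL1CAM_slice), with medians of -0.38 and -0.10 without replicate 1 or 2 of shL1CAM_slice, -0.37 without replicate 2 of shControl_dish and -0.12 without replicate 1 of shL1CAM_dish. Basement membrane and matrix genes differed by -0.30 (camera adjusted p = 0.0027, adjusted p = 0.851 with an estimated correlation, 0.986 without replicate 1 of shL1CAM_dish, 0.198 without replicate 1 of shL1CAM_slice, and 0.194 with the length trend removed), with medians of -0.08 and -0.53 without replicate 1 or 2 of shL1CAM_dish and -0.16 without replicate 2 of shL1CAM_slice. NF-kB targets and inflammatory cytokines differed by 0.245 (camera adjusted p = 0.00337, adjusted p = 0.373 with an estimated correlation, and 0.248 without replicate 1 of shL1CAM_slice), with medians of 0.14 without replicate 2 of shControl_dish and 0.11 without replicate 1 of shControl_slice. The type I interferon response differed by -0.19 (camera adjusted p = 0.0148, and adjusted p = 0.851 with an estimated correlation), with 0.587 and 0.364 without replicate 1 of shControl_dish or of shL1CAM_dish, 0.0642 without replicate 2 of shControl_slice and 0.488 without replicate 1 of shL1CAM_slice, and medians of -0.08 and -0.39 without replicate 1 or 2 of shControl_dish and -0.10 and -0.36 without replicate 1 or 2 of shL1CAM_dish. G1/S genes differed by 0.12 (camera adjusted p = 0.0216, and adjusted p = 0.851 with an estimated correlation), with 0.542 and 0.25 without replicate 1 of shControl_dish or of shL1CAM_dish, 0.211 without replicate 2 of shControl_slice and 0.386 without replicate 1 of shL1CAM_slice, and medians of 0.06 without replicate 1 of shControl_dish, 0.05 without replicate 2 of shControl_slice and 0.07 without replicate 1 of shL1CAM_dish. Neurite-type cell adhesion molecules differed by -0.23 (camera adjusted p = 0.024, and adjusted p = 0.851 with an estimated correlation), with 0.0806 and 0.0517 without replicate 2 of shControl_dish or of shControl_slice, 0.629 without replicate 1 of shL1CAM_dish, 0.856 without replicate 2 of shL1CAM_slice, and 0.201 with the length trend removed, and medians of -0.05 and -0.42 without replicate 1 or 2 of shL1CAM_dish and -0.52 and 0.0083 without replicate 1 or 2 of shL1CAM_slice.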

How the results depend on the processing

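The library weights and the removal of the transcript-length trend were tests chosen only after the results were seen. A fit without a library leaves its group with 1 library, which is assumed to vary like the other groups. Without each of the 8 libraries in turn, the count of genes past the threshold ran from 7 to 6109 for the slice with control shRNA, from 341 to 7503 for the slice with L1CAM shRNA, from 4 to 6896 for the knockdown on the slice, from 0 to 1437 for the knockdown in the dish and from 0 to 4136 for the interaction. The counts of lists ran from 11 to 14, 9 to 15, 3 to 10, 8 to 16 and 5 to 14 in the same order. The shared slice response ran from 7 to 4323 genes, the shared knockdown effect from 0 to 998, and the slice genes that the knockdown opposed from 0 to 1816. The log2 fold change of L1CAM in the dish ran from -2.37 to -1.86. A library outside the compared groups changes none of their fold changes, so it acts on a count through the shared spread. Which library of a group was left out also moved the counts, and the cause of that was not tested.

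With the 4 libraries compared alone, the counts were 6808 for the slice with control shRNA, 510 with L1CAM shRNA, 0 for the knockdown on the slice (limma, with 1126 genes at an unadjusted p under 0.05, where edgeR and DESeq2 on all 8 libraries called 86 and 342) and 824 in the dish. This fit does not apply to the interaction. With library weights they were 7032, 975, 48 and 1011, and the overlaps were 967 for the slice response and 46 for the knockdown effect. With the transcript-length trend removed the knockdown counts were 175 on the slice and 92 in the dish, 63 genes were shared, and 42 slice genes were opposed. Of the lists called for the knockdown, 8 of 9 on the slice and 11 of 12 in the dish stayed called by camera with the trend removed. With no filter the knockdown counts were 15 on the slice and 16 in the dish, and with a mean of at least 50 they were 40 and 14, with 13 shared and 10 opposed. DESeq2 gave 342 on the slice and 184 in the dish, edgeR 77 in the dish, and a pseudocount of 10 gave 62 in the dish. The fit of the 4 libraries compared keeps the fold changes of the main fit. Its counts therefore differ through the estimate of the spread and the number of libraries behind it. The cause of the other differences was not tested.

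With an estimated correlation camera called 1 list for each slice response, 0 for the knockdown on the slice, 0 in the dish and 0 for the interaction. Fry called 18 lists for the slice with L1CAM shRNA, 1 for the knockdown on the slice, 3 in the dish and 0 for the interaction. The replicate block gave 1814 and 2777 genes for the slice responses, 85 and 46 for the knockdown and 0 for the interaction. The correlations of replicate differences between groups ran from -0.377, between shControl_dish and shL1CAM_dish, to 0.194, between shControl_dish and shL1CAM_slice. The block joins replicates by their number, so it does not cover a pairing in the reverse order.

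For the named genes, 456 results made 9938 comparisons with alternatives. Of these, 8488 kept their direction and their side of the threshold, 1133 were no longer past it, 316 came past it and 1 changed sign. That was L1CAM on the slice against the dish with control shRNA, a change that was not called, which ran from -0.12 to 0.012 without 1 library and was above 0 without replicate 1 of shControl_dish. For genes near 0 reads the floor of 3 reads, a normalized count of 2.75 to 3.57, limits what a fall can show.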

Other observations

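The tests of mouse brain RNA in replicate 2 of shL1CAM_slice, of the length trend for the YAP/TAZ targets and of serum were chosen only after the result was seen.

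In lists that were not called with all 8 libraries, single members still changed on the slice in control cells. Of 25 genes of the integrated stress and amino acid response 9 fell and 3 rose (12 and 3 adjusted over the list alone, 14 and 5 without replicate 2 of shL1CAM_slice, where the list was called at adjusted p = 0.0375), with asparagine synthetase (ASNS, -1.53) and the amino acid transporters SLC7A5 (-1.07) and SLC1A5 (-0.99) among the falls. Of 14 heat shock proteins 5 fell and 0 rose (5 and 2 adjusted over the list alone), HSP90AA1 (-1.16) and HSPD1 (-1.07) among them. Of 21 hypoxia genes 5 fell and 2 rose (7 and 4 adjusted over the list alone), with ADM (-1.93) and the glucose transporter SLC2A1 (-1.07) lower. Of 19 epithelial genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), the claudin CLDN4 (2.91) being one. Of 14 antigen presentation genes 3 fell and 1 rose (3 and 2 adjusted over the list alone), with the peptide transporters TAP2 (-1.43) and TAP1 (-0.87) lower and NLRC5 (0.91) higher. Without replicate 1 of shControl_dish each of these calls was lost, those of ASNS, SLC1A5, SLC2A1, TAP1 and NLRC5 also without replicate 2 of shControl_dish or either library of shControl_slice, those of SLC7A5, HSP90AA1 and HSPD1 also without either library of shControl_slice, and that of ADM also without replicate 1 of shControl_slice.

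L1CAM shRNA lowered the cell-cycle inhibitor CDKN1A by a log2 fold change of -1.31 on the slice (limma adjusted p = 0.02) and -1.45 in the dish (adjusted p = 0.017), NDRG1 by -1.31 and -1.21, and the laminin chain LAMB3 by -1.39 and -1.48. The aldo-keto reductase AKR1C3 rose on the slice (1.14, limma adjusted p = 0.0427). These calls were lost without any 1 library of shControl_dish, shControl_slice or shL1CAM_dish.

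YAP1 and WWTR1, which encode YAP and TAZ and were chosen after their values were seen, were higher on the slice with either shRNA. With L1CAM shRNA YAP1 rose by 1.48 ± 0.30 (limma adjusted p = 0.0125) and WWTR1 by 0.71 ± 0.20 (adjusted p = 0.039). The 2 libraries of shL1CAM_slice lay far apart, YAP1 at 12093 and 5472 and WWTR1 at 5760 and 3600. The values that follow are for control cells. YAP1 rose by 1.86 ± 0.30 (limma adjusted p = 0.00751) and WWTR1 by 0.83 ± 0.20 (adjusted p = 0.0294). Without 1 library the YAP1 change ran from 1.77 to 1.94 and passed in 4 of 8 fits, and WWTR1 ran from 0.79 to 0.88 and passed in 2 of 8.

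The YAP/TAZ list was called lower on the slice with either shRNA, with adjusted p = 0.442 in control cells and 0.488 with L1CAM shRNA with an estimated correlation. With the length trend removed, the list had a camera adjusted p = 1.1e-05 and a median of -0.55 in control cells. The control libraries differ little in that trend, so its removal could change little there. With L1CAM shRNA, where replicate 2 on the slice carries the trend, all 9 called lists stayed called by camera with the trend removed, this list among them. That argues against a length trend as the whole cause. A few strong members as the cause are argued against by the 21 members outside the 3 largest falls, with camera adjusted p = 0.000522 in control cells and adjusted p = 3.75e-05 with L1CAM shRNA. Less serum in the slice medium and the brain tissue itself cannot be told apart, because medium, serum, substrate and time change together. Immediate early genes, which serum induces, had a median of 0.26 in control cells and 0.32 with L1CAM shRNA, while the MRTF/SRF list, which serum also induces, was called lower in control cells (adjusted p = 0.0285, and adjusted p = 0.661 with an estimated correlation) and not with L1CAM shRNA (adjusted p = 0.0603).

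Replicate 2 of shL1CAM_slice differed from replicate 1 by an SD of 0.637 across genes. Its length trend as the whole cause is argued against by an SD of 0.566 after removal, against at most 0.298 in the other groups. Lower depth is argued against by the read totals, 13486212 here and 13899903 in replicate 2 of shControl_slice, whose pair had an SD of 0.218. Thinning that pair to the reads of the shallowest library removed few reads, so its SD of 0.226 afterwards adds little. More mouse brain RNA is not settled, since brain markers lay 1.85 ppm of the signal below the lowest other slice library, within the 2.94 ppm by which the spread between replicates lets 2 libraries differ. No biological explanation was tested, and what sets this library apart stays open.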
